A study of freshwater metagenome with 34 samples.

How the data were processed

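The series measured gene expression in benthic river biofilms, the mixed communities of algae, bacteria and other microbes that grow attached to submerged surfaces. Per the labels, the biofilms grew on glass slides in tanks for 5 weeks, either with 4 µg/L of diuron (called stressed) or without it (called non-stressed). Diuron is a herbicide that blocks electron transport at photosystem II. Afterwards the biofilms were held for 1 hour at 1 of 9 diuron concentrations, namely 0, 0.0001, 0.001, 0.01, 0.1, 1, 10, 50 and 100 µg/L. Each of the 34 libraries was made from total RNA after removal of ribosomal RNA with bacterial and plant probes, with a strand-specific kit and paired-end Illumina sequencing of a common pool.

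The authors deposited 1 table of estimated counts, the number of read pairs assigned to each transcript contig, for 3,502,153 contigs and 34 columns. Per the submitters' processing notes the counts came from kallisto 0.43.0, which shares a read among the contigs it matches. The identifiers have the prefix and form that the Trinity assembler gives, with a cluster part and an isoform part, and fall into 2,376,397 clusters. The assembler's version, its filters, the normalization before assembly and any annotation are not given in the sources used here. Of the values above 0 in the deposited table of estimated counts, 71.6% were whole within a tolerance of 1e-06, and all were rounded to whole numbers before testing. Because kallisto divides reads among similar contigs, the count of an isoform or of a close homologue from another species is uncertain, more so than the sum over its cluster.

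Columns were matched to libraries by name. The column names carry a prefix for the community, the rank of the concentration and a replicate number. Only 1 assignment of the 2 prefixes gives the same number of columns per concentration as the titles give libraries, so the prefixes were read that way. In the 2 groups with 1 library the column is numbered 2 where the title says replicate 1. The columns not matched to a library numbered 0. The libraries form 18 groups, of which 16 hold 2 libraries and 2 hold 1 (non-stressed at 0.001 µg/L and stressed at 10 µg/L). The labels do not say how many tanks there were or whether replicates came from separate tanks, so p-values measure the spread between these libraries only, and the 5-week exposure and the tank in which it took place are not separable. Replicates of 1 group differed far beyond counting noise (chi-square per contig from 38.4 to 87.7), so none was the same library sequenced again. Whether 2 libraries came from 1 RNA sample or 1 biofilm was not tested.

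Totals ranged from 28,975,155 to 41,496,006 counts per library. Contigs were tested where edgeR's filterByExpr kept them with a minimum count of 10 and the 2 communities as groups, which left 278,973 contigs, 7.97% of the table. These held 68.8% to 84.6% of the counts of a library. The primary model used edgeR 4.0.16 in R 4.3.3, with TMM factors (0.737 to 1.42), a common and trended dispersion, the quasi-likelihood F-test and 1 mean for each of the 18 groups, which leaves 16 residual degrees of freedom. The biological coefficient of variation at the median trended dispersion was 0.945. P-values were adjusted by the Benjamini-Hochberg method over all contigs tested in a comparison, with a threshold of 0.05. A standard error is the log2 fold change divided by the square root of F.

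Comparisons fixed before the data were examined were the mean of the 9 stressed groups against the mean of the 9 non-stressed groups, the same difference at 0 µg/L, a linear contrast over the rank of the concentration (0 to 8) within each community, the difference of these 2 trends, a test of any difference among the 9 concentrations within each community, and the 16 contrasts of 1 concentration against 0 µg/L. The estimate of a trend is the fitted change from the lowest to the highest rank. The mean of the 2 trends was added after the data were seen. Distances between libraries were analysed by PERMANOVA (vegan 2.7.1, 9999 permutations) on Bray-Curtis distances of contig shares, with the concentration permuted within communities. Shannon diversity (natural log), the number of contigs with a count and the share of counts in the 100 most abundant contigs were computed after thinning each library to the smallest total and compared by permutation tests of 100000 resamples within concentrations. Mean levels of contig sets were computed on log2(CPM + 0.5) with TMM-scaled library sizes, and compared between communities by an exact permutation test over the 362880 orders of the 9 concentrations. CPM values of single contigs are counts scaled by the TMM-scaled total over the tested contigs, as edgeR gives them. Mean levels of contig sets, and folds against a floor of 3 counts, used the TMM-scaled total over all contigs instead. The 2 scales therefore differ, and a printed fold is not the ratio of the printed CPM to that floor.

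The 23 gene lists chosen beforehand (photosystems, antenna proteins, chlorophyll synthesis, carbon fixation, stress responses, and markers of diatoms, fungi, bacteria and animals among them) could not be tested, because the table holds identifiers that are not paired with gene names, functions or organisms, and no reference was used here. The number of lists tested was 0. By the rule fixed beforehand for such a table, at most 2 rising and 2 falling contigs are named per comparison, those with the smallest adjusted p.

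Alternatives were DESeq2 size factors or library totals in place of TMM, no filter or a minimum count of 50, limma-voom (limma 3.58.1), DESeq2 1.42.0, the replicate number as a block, sums over assembler clusters, a straight-line model of rank, the logarithm of the concentration (with 0.0001 added), a minimum log2 change of 1, other distances, and leaving out each library in turn. The bias-adjusted form of edgeR's test, sums over clusters with the replicate block, sets without 2 stressed libraries, each concentration left out of the mean trend in turn and the mean levels over the concentrations were chosen after seeing the data. The steps were tested on simulated counts with the means, sizes and dispersions of these libraries and 200 changed contigs per comparison. For the difference between communities, 11.3% of contigs changed 4-fold, 74.1% of those changed 16-fold and 98.0% of those changed 64-fold were recovered among 238,613 simulated contigs, with 5 calls among unchanged contigs. For the non-stressed trend 0% were recovered at each of these sizes. With 10% of contigs changing along the concentration, 4.84%, 44.4% and 81.3% of the 4-, 16- and 64-fold trends were recovered among 237,508 simulated contigs, with 490 calls among unchanged contigs.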

Results

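Gene expression was measured in 34 RNA-seq libraries of river biofilm, 17 from communities grown for 5 weeks with 4 µg/L of diuron (stressed) and 17 from communities grown without it (non-stressed). Within each community the libraries covered 9 diuron concentrations applied for 1 hour, from 0 to 100 µg/L, with 2 libraries per concentration except for 1 at 0.001 µg/L in the non-stressed and 1 at 10 µg/L in the stressed community. Libraries held 28,975,155 to 41,496,006 estimated counts, and between 1,088,929 and 1,937,882 assembled contigs had a count. The contigs carry assembler identifiers only, so the transcripts are described by contig and not by gene or organism. The design asks how the 5-week exposure changed the transcripts of the community, which transcripts followed the 1-hour concentration, and whether that response differed between the communities.

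The 2 communities differed in their transcripts as a whole. Community accounted for 18.8% of the variation in Bray-Curtis distance between libraries (permutation test, p = 1e-04, the smallest that its permutations can give, adjusted p = 4e-04 over 4 tests). Libraries of different communities lay at a mean distance of 0.524 ± 0.0572 (SD, 289 pairs), against 0.444 ± 0.0727 for libraries of 1 community at different concentrations (256 pairs) and 0.429 ± 0.0640 for replicates of 1 group (16 pairs). Replicates were not closer to each other than libraries of other concentrations in the same community beyond chance (one-sided permutation test, p = 0.179). The rank of the acute concentration accounted for 4.97% of the variation (permutation p = 0.0145, adjusted p = 0.0290). Within a community it took 8.82% in the non-stressed (permutation p = 0.136) and 9.49% in the stressed libraries (p = 0.0909), neither of which passed the threshold. Leaving out single libraries gave 4.30% to 5.79%, and the adjusted p was not under 0.05 for 5 of the 34, among them both non-stressed libraries at 100 µg/L (permutation test, adjusted p = 0.109 without the first and 0.0700 without the second). Without the first stressed libraries at 50 and 100 µg/L the rank took 4.05% (permutation p = 0.0634, adjusted p = 0.127).

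**Figure D1:**
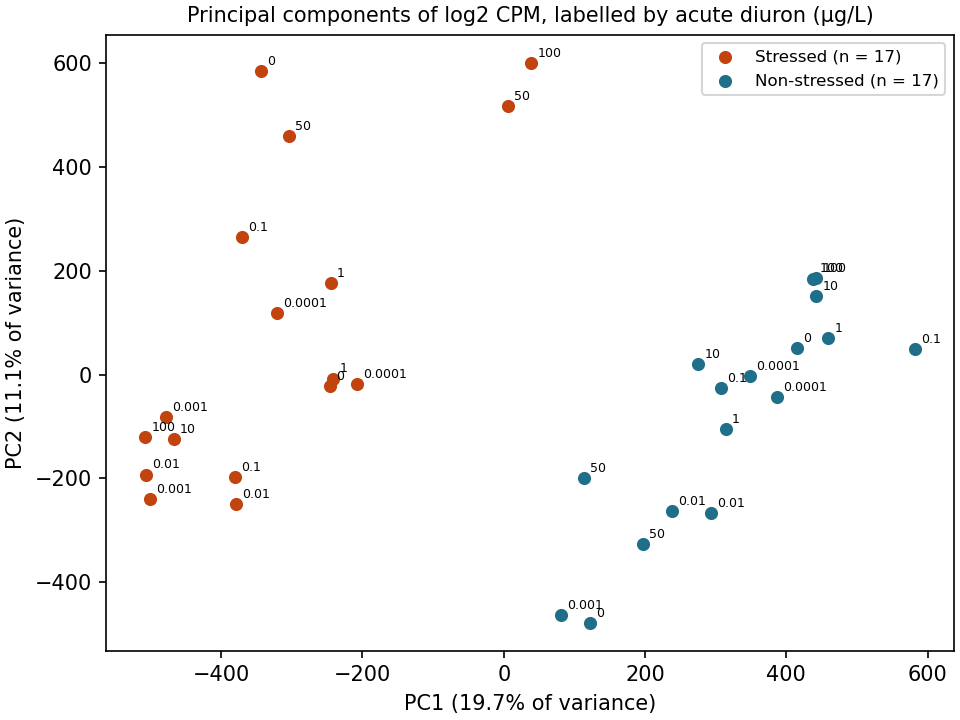
Principal components of log2 CPM for the 34 libraries, with PC1 (19.7% of the variance) on the horizontal and PC2 (11.1%) on the vertical axis; each point is 1 library, coloured by community and labelled with its acute diuron concentration in µg/L. The stressed libraries lie to the left of the non-stressed ones on PC1, and the first stressed libraries at 50 and 100 µg/L (PC1 scores of 5.85 and 38.9) lie nearest to them.

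Many contigs differed in abundance between the communities after the 5-week exposure. Of 278,973 contigs tested, 78,262 (28.1%) differed between the communities with an adjusted p under 0.05 in edgeR's quasi-likelihood test, 39,306 of them higher and 38,956 lower in the stressed community. The balance of directions turned with the scaling, to 43,591 higher and 36,345 lower with DESeq2's size factors and 34,389 higher and 39,932 lower with library totals, and DESeq2's test called 60,520 higher and 49,156 lower. Without the first stressed libraries at 50 and 100 µg/L more contigs were lower than higher in the stressed community. The table holds no measure of how abundant each organism was. A difference in expression is therefore not separated from a difference in the organisms present. The differences were large. The median absolute log2 fold change of the called contigs was 2.16, with a median standard error over all tested contigs of 0.52; 76,689 differed at least 2-fold, 43,914 at least 4-fold and 7,468 at least 16-fold. The count moved with the filter, to 210,444 of 3,482,727 contigs without one and 20,603 of 63,679 contigs with a minimum count of 50.

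Contigs higher in the stressed community held 21.4% ± 4.70 (SD, n = 17) of the counts of a stressed library and 5.99% ± 1.34 (n = 17) of a non-stressed one. Contigs higher in the non-stressed community held 21.9% ± 3.90 of the counts of a non-stressed library and 5.51% ± 2.41 of a stressed one. These shares come from the libraries on which the contigs were called and are therefore apart by construction to some degree. Among the 100 contigs with the largest mean share of counts, 12 were higher in the stressed and 19 higher in the non-stressed community, and the other contigs of that list did not pass the threshold. The part of contigs called rose with abundance, from 19.5% in the lowest of 5 equal classes of mean CPM to 35.8% in the highest. With TMM scaling the part of calls that were higher in the stressed community rose as well, from 44.0% to 54.6%. That part was not computed by class under the other scalings. With a minimum count of 50, 10,287 contigs were higher and 10,316 lower.

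Both communities nevertheless had many contigs in common. The 98,591 contigs with a count in all 34 libraries held 56.8% of the counts. Their levels could differ widely, as TRINITY_DN27463_c1_g1_i4 stood at 199 CPM in the non-stressed and 1.76 CPM in the stressed libraries. Contigs present throughout 1 community with 0 counts in the other held few counts, which the rule itself favours. It leaves out abundant contigs with any count in the other community, such as TRINITY_DN1329942_c0_g1_i2 with 13,424 stressed and 11 non-stressed counts. A count in all 17 stressed and in none of the 17 non-stressed libraries was seen for 273 contigs, with 0.0261% of the stressed counts, and the reverse for 33 contigs, with 0.00354% of the non-stressed counts. Neither pattern occurred in any of 100 splits in which the community names were shuffled within concentrations (0 contigs). With a count in at least 12 of the 17 libraries of 1 community and none of the other, 11,112 contigs belonged to the stressed and 3,562 to the non-stressed community, where shuffled names gave at most 149 and 271. They held 0.299% of the stressed and 0.0956% of the non-stressed counts.

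The contig with the smallest adjusted p, TRINITY_DN1329942_c0_g1_i2, stood at 28.1 ± 20.3 CPM (SD, n = 17) in the stressed and 0.0244 ± 0.0253 CPM (n = 17) in the non-stressed libraries, a log2 fold change of 10.40 (SE 0.56, adjusted p = 1.07e-08). TRINITY_DN27326_c0_g1_i14 stood at 40.8 ± 28.1 CPM in the stressed libraries and at 0.0508 ± 0.126 CPM in the non-stressed, where 5 of 17 libraries had a count (log2 fold change 11.30, SE 0.66, adjusted p = 3.34e-07). With so few counts in the non-stressed libraries the sizes of both changes depend on the method. Limma-voom gave 10.07 for the second contig. For the first, with 11 counts over the non-stressed libraries, the alternatives gave log2 fold changes of 9.41 to 10.53. In the other direction, TRINITY_DN27463_c1_g1_i4 fell from 199 ± 123 CPM in the non-stressed to 1.76 ± 1.67 CPM in the stressed libraries (log2 fold change −6.60, SE 0.55, adjusted p = 6.76e-07). TRINITY_DN440783_c1_g1_i1 fell from 14.9 ± 5.62 to 1.63 ± 0.635 CPM (log2 fold change −3.26, SE 0.28, adjusted p = 7.45e-07). In each of these 4 contigs every stressed library lay on the same side of every non-stressed library.

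**Figure D2:**
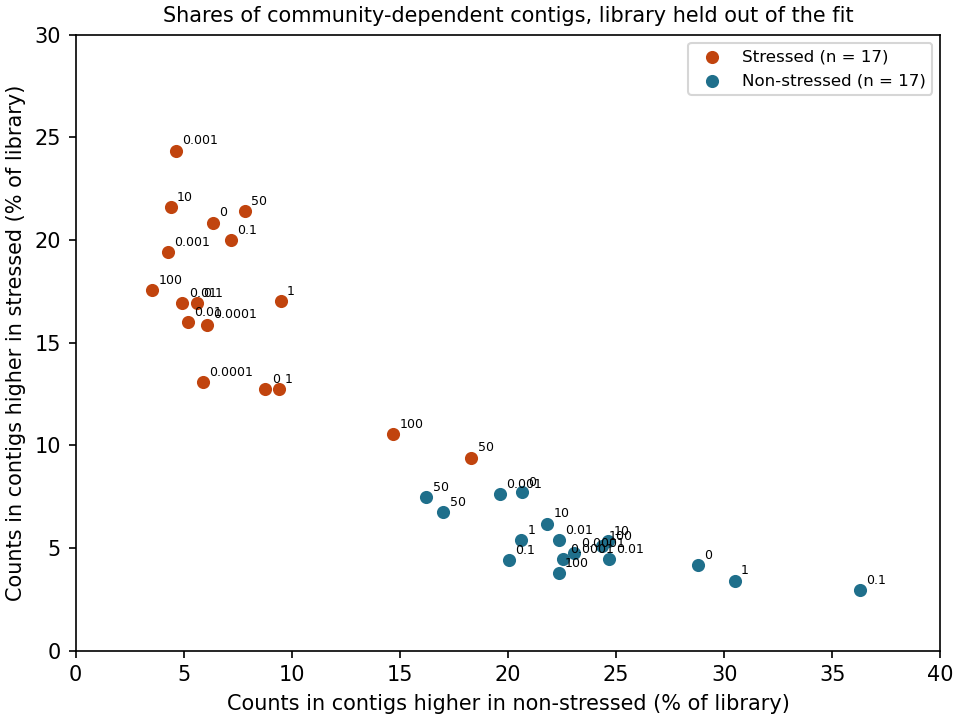
Share of the counts of each library in contigs higher in the non-stressed (horizontal axis, % of counts) and higher in the stressed community (vertical axis, % of counts), where the contigs were called from a fit that held neither that library nor the others of its concentration, nor the first stressed libraries at 50 and 100 µg/L, which were left out of every fit; each point is 1 library, labelled with its acute concentration in µg/L. The log2 ratio of the 2 shares ran from 0.440 to 2.39 in 15 stressed libraries and from −3.62 to −1.11 in the 17 non-stressed, and was −0.960 and −0.475 in the first stressed libraries at 50 and 100 µg/L.

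The 5-week exposure was also compared in the libraries that received no acute diuron, where 2 stressed stood against 2 non-stressed libraries. A single contig, TRINITY_DN32220_c0_g1_i16, passed the threshold (adjusted p = 0.0259). It had 15.8 ± 7.98 CPM (SD, n = 2) in the non-stressed libraries and 0 counts in both stressed ones, at least 285-fold lower when the stressed libraries are set at 3 counts over the group. All contigs of its cluster, of which 7 were tested, together had 1861 and 1298 counts in those 2 libraries, so the zero belongs to the isoform and not to the cluster. At an unadjusted p under 0.05 the comparison gave 29,810 contigs, and its median standard error was 1.5 on the log2 scale against 0.52 over all concentrations. The call ended on leaving out any of 12 single libraries or the first stressed libraries at 50 and 100 µg/L, and limma-voom did not call this contig (adjusted p = 0.0700). Limma-voom called 19 other contigs and DESeq2 9,113 contigs.

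A small set of contigs differed among the 1-hour concentrations by edgeR's main test, and its mean level had a like profile in both communities. The test of any difference among the 9 concentrations called 36 contigs in the non-stressed and 29 in the stressed community, and 26 contigs, from 22 assembler clusters, were called in both, where independent lists of these sizes would share 0.00374. Both tests use 1 fit with the same dispersion for a contig, so the lists are not independent and that number is a rough reference only. These 26 contigs did not rise or fall steadily with the concentration. In the non-stressed community their mean log2(CPM + 0.5) was 1.15 at 0, 6.58 at 0.0001, 0.40 at 0.001, 3.66 at 0.01, 6.62 at 0.1, 1.5 at 1, 2.36 at 10, 5.56 at 50 and 6.10 at 100 µg/L. In the stressed community the values in the same order were 1.69, 6.31, 2.12, 3.58, 6.80, 2.25, 1.01, 6.60 and 7.26. The spread of this mean between replicates was 0.59 (SD within groups). The 4 concentrations of 0.0001, 0.1, 50 and 100 µg/L lay above the other 5 by 4.40 on average in the non-stressed and by 4.62 in the stressed community, and the lowest of the 4 was above the highest of the 5 by 1.91 and 2.73. These 4 were picked from the profile itself, so such gaps are there by construction to some degree. Without the first stressed libraries at 50 and 100 µg/L the tests called 17 and 7 contigs, and without single libraries 11 to 41 and 6 to 129. DESeq2's likelihood ratio test called 5,633 and 12,102 contigs. A minimum count of 50 gave 50 and 112 contigs, the bias-adjusted test 62 and 719, and sums over clusters 42 and 430 clusters. Whether the further calls of these settings share the profile was not tested.

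The likeness of the communities was then checked with contigs chosen in only 1 of them. Over the 9 concentrations, the mean level of the 36 contigs called in the non-stressed community correlated with their mean level in the stressed community, whose libraries were not compared in choosing them, with r = 0.931 (exact permutation p = 0.00328) and rho = 0.767 (exact p = 0.0214), and with r = 0.937 without the 2 concentrations farthest from the median. The 29 contigs called in the stressed community gave r = 0.928 (exact p = 0.00330) and rho = 0.800 (exact p = 0.0138). Over the 5 contig sets examined the adjusted p was 0.00330 for both values of r. The mean level of the 36 contigs in the stressed community was not related to the rank of the concentration (r = 0.342, exact p = 0.356). The 26 shared contigs took between 0.189% and 0.841% of the counts in the 16 libraries at the 4 concentrations of high level, and between 0.00554% and 0.1% in the other 18 libraries. Contigs and concentrations were both chosen from these libraries, so the shares are apart by construction to some degree and are no part of the check.

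**Figure D3:**
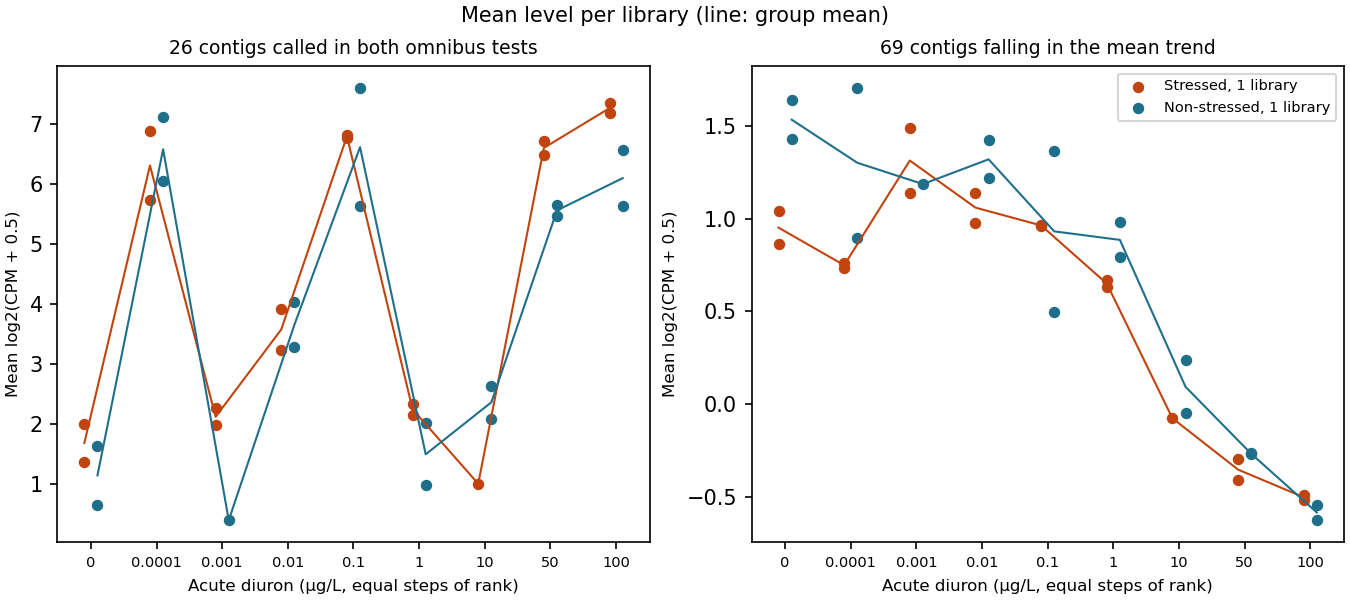
Mean log2(CPM + 0.5) per library (vertical axes) against acute diuron in µg/L, in equal steps of rank (horizontal axes), for the 26 contigs called in both tests of any difference among concentrations (left) and the 69 contigs that fell in the mean trend (right); points are libraries, lines join group means, colours are the communities. The left set is high at 0.0001, 0.1, 50 and 100 µg/L in both communities, and the right set is lowest at 50 and 100 µg/L.

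A steady response to the concentration was sought next. No contig passed the threshold for a trend over the rank of the concentration in either community by edgeR's test. The non-stressed community gave 0 contigs (smallest adjusted p = 0.172; 29,507 contigs at an unadjusted p under 0.05) and the stressed community 0 contigs (smallest adjusted p = 0.195; 24,473 contigs at an unadjusted p under 0.05). DESeq2 called 5,509 and 4,891 contigs, limma-voom 0 and 0, and the straight-line model 55 and 219. The median standard error of a trend was 1.11 on the log2 scale in each community, and simulated non-stressed trends of up to 64-fold were not recovered when few contigs carried one. When 10% of the contigs carried a trend, 44.4% of the 16-fold and 81.3% of the 64-fold trends were recovered. The 0 calls of the non-stressed community therefore speak against large steady trends in as many as 10% of the contigs. They leave open large trends in fewer contigs. The simulated changes followed a straight line over the rank in contigs drawn independently, so changes of another shape were not covered.

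The mean of the 2 trends, a comparison added after the data were seen, called 96 contigs, 27 rising and 69 falling. All had the same direction in both communities, which choosing them by the mean favours. The excess of falling contigs depended on the setting, with 56 rising and 50 falling in limma-voom, 174 and 153 at a minimum count of 50, and 74 and 71 with 10 µg/L left out of the contrast. The falling contigs also depended on the libraries at 100 µg/L. The test called 0 falling contigs without the first and 2 without the second non-stressed library, 4 without the first stressed one, and 1 without the first stressed libraries at 50 and 100 µg/L. The 69 falling contigs, from 64 clusters, had a median log2 change of −5.50 from the lowest to the highest rank. Their level was lower from 10 µg/L upwards. Their mean log2(CPM + 0.5) in the non-stressed community stayed between 0.89 and 1.53 from 0 to 1 µg/L and was 0.09 at 10, −0.27 at 50 and −0.58 at 100 µg/L. In the stressed community it stayed between 0.65 and 1.31 up to 1 µg/L and was −0.08, −0.35 and −0.50 at 10, 50 and 100 µg/L. Their share of counts was 0.0345% ± 0.00442 (SD, n = 4) at 0 and 0.00287% ± 0.000568 (n = 4) at 100 µg/L. These levels and shares come from the libraries on which the contigs were chosen, so a fall is there by construction to some degree. The 0.5 added to the CPM also limits how low the levels can go. TRINITY_DN2270533_c0_g1_i1 stood at 2.67 ± 2.60 CPM (SD, n = 4) at 0 and 0.126 ± 0.0383 CPM at 100 µg/L (log2 change −4.53, SE 0.56, adjusted p = 0.00393). TRINITY_DN7732_c0_g1_i4 stood at 5.89 ± 1.05 CPM at 0 and 0.172 ± 0.158 CPM at 100 µg/L (log2 change −6.70, SE 0.86, adjusted p = 0.00608).

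The 27 rising contigs, from 25 clusters, behaved otherwise. Of these, 12 were also called in a test of any difference among concentrations, against 0 of the 69 falling contigs. TRINITY_DN16979_c0_g1_i1 had the smallest adjusted p of these, shared with TRINITY_DN22892_c1_g1_i5 (log2 change 3.91, SE 0.47, adjusted p = 0.00393), but its mean CPM was 2.88 ± 1.40 (SD, n = 4) at 0, 141 ± 63.0 at 0.0001, 4.2 ± 4.23 (n = 3) at 0.001, 263 ± 120.4 at 0.1, 6.52 ± 4.38 at 1 and 290 ± 141 at 100 µg/L. The second contig (log2 change 5.16, SE 0.62, adjusted p = 0.00393) stood at 0.0949 ± 0.0709 CPM at 0, 25.1 ± 14.5 at 0.0001, 0.749 ± 0.411 at 1 and 41.3 ± 22.1 at 100 µg/L. The levels of these 2 contigs therefore did not rise steadily over successive concentrations. The rising calls depended on low concentrations too. With 0 µg/L left out of the contrast 3 contigs rose and 38 fell, and with 0.001 µg/L left out 4 rose and 35 fell. The mean trend rested on the highest concentrations, since 0 contigs passed when 50 or 100 µg/L was left out of the contrast, and 5 passed without the first stressed libraries at those concentrations. Leaving out single libraries gave 2 contigs (without the first non-stressed library at 100 µg/L) to 269 (without the second stressed library at 100 µg/L), with a move of over 1.5 times for 23 of 34 libraries, and DESeq2 called 12,858 contigs. None of the 4 named contigs passed in the straight-line model (adjusted p = 0.133 and 0.173 for the falling and 0.542 and 0.639 for the rising ones), where the changes of the rising ones were 2.10 and 1.84 (log2). TRINITY_DN2270533_c0_g1_i1 also lost its call without the first stressed libraries at 50 and 100 µg/L (adjusted p = 0.0538). The calls of the falling contigs also ended without non-stressed libraries at 100 µg/L, the first for TRINITY_DN2270533_c0_g1_i1 (adjusted p = 0.0637) and either for TRINITY_DN7732_c0_g1_i4 (up to 0.0890).

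**Figure D4:**
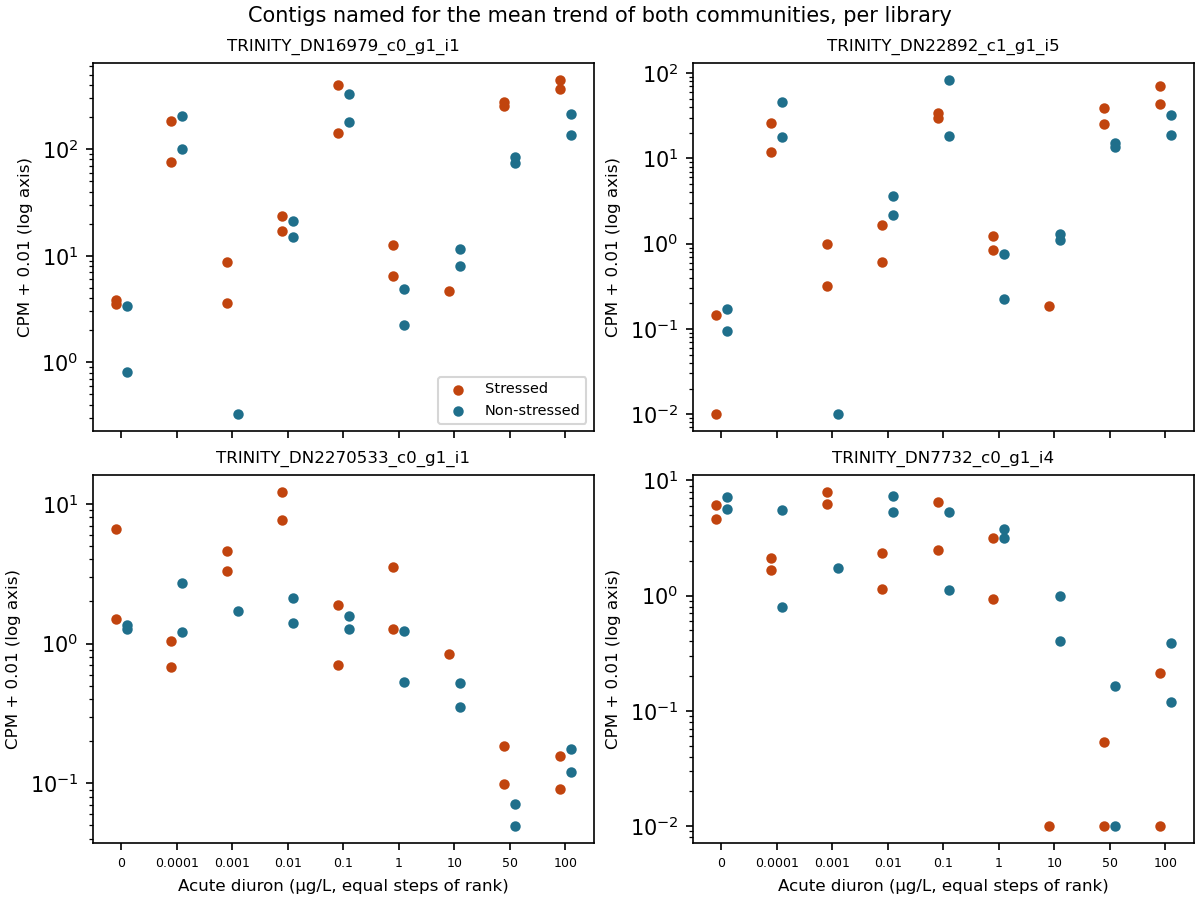
CPM plus 0.01 on a log axis (vertical) against acute diuron in µg/L in equal steps of rank (horizontal) for the 4 contigs named in the mean trend, with 1 point per library and colours for the communities. The upper contigs are high at 0.0001, 0.1, 50 and 100 µg/L, and the lower contigs are low at 50 and 100 µg/L in both communities.

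The response to the acute concentration was compared between the communities. The difference of the 2 trends gave 0 contigs by edgeR's test (smallest adjusted p = 0.486; 19,893 contigs at an unadjusted p under 0.05), against 2,248 by DESeq2, 0 by limma-voom and 67 by the straight-line model. The median standard error of that difference was 1.55 on the log2 scale. Across contigs, which are not independent replicates, the trend estimates of the 2 communities correlated with r = 0.210 and rho = 0.214. This was within the range of −0.276 to 0.265 that shuffled concentrations gave (permutation p = 0.178, adjusted p = 0.534 over 3 relations). Neither the non-stressed (r = −0.0150, adjusted p = 0.894) nor the stressed trend (r = −0.0601, adjusted p = 0.894) was related to the difference between communities.

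Each concentration above 0 was set against 0 µg/L within its community, with 2 control libraries shared by 8 contrasts. Of the 16 contrasts, 14 called 0 contigs in edgeR's test, with 6,482 to 22,090 contigs at an unadjusted p under 0.05 over these; limma-voom called 0 to 41 and DESeq2 493 to 3,064 contigs in the same 14. In simulated counts 0% of 64-fold changes between 100 and 0 µg/L in the non-stressed community were recovered when few contigs changed, so large changes in few contigs remain open. In the stressed community 1 and 50 µg/L called 1 contig each, and in both it was TRINITY_DN32220_c0_g1_i16, the contig without counts in the 2 stressed libraries at 0 µg/L. It had 23.3 ± 10.9 CPM (SD, n = 2) at 1 µg/L and 16 ± 1.83 CPM (n = 2) at 50 µg/L, at least 420.5-fold and 310-fold higher with the controls set at 3 counts over the group (adjusted p = 0.0146 and 0.0254). Limma-voom did not call it in either contrast (adjusted p = 0.734 and 0.0727). These calls and that at 0 µg/L rest on the same pair of control libraries, and without either of the 2 none of the contrasts called a contig.

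The most abundant contigs held a smaller share of the counts in the stressed libraries, but this depended on single libraries. The 100 most abundant contigs of a library held 12.2% ± 3.96 (SD, n = 17) of its counts in the stressed and 15.7% ± 4.70 (n = 17) in the non-stressed community (permutation test, two-sided, p = 0.0143, adjusted p = 0.0429 over 3 measures). The adjusted p rose above 0.05 on leaving out any of 22 single libraries and reached 0.108 without the stressed library at 10 µg/L. The first library had the higher share in every group of 2 libraries but the non-stressed at 100 µg/L. The tests of this share did not take the replicate number into account. Shannon diversity was 11.4 ± 0.472 in the stressed and 11.2 ± 0.561 in the non-stressed libraries (permutation p = 0.219, adjusted p = 0.328). The number of contigs with a count did not differ beyond the spread either (1,547,900 ± 213,300 against 1,531,400 ± 224,500, permutation p = 0.806).

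Within communities, the share of the 100 most abundant contigs against the rank of the concentration gave r = 0.412 (permutation p = 0.101) and rho = 0.337 (p = 0.184) in the non-stressed, and r = 0.483 (p = 0.0509) and rho = 0.431 (p = 0.0865) in the stressed libraries, n = 17 each; no adjusted p over the 6 relations was under 0.223. Without 0 and 100 µg/L r was 0.0179 in the non-stressed and 0.569 in the stressed libraries. Pooled within communities, which was chosen after seeing these values, the relation gave r = 0.443 and rho = 0.361 (permutation p = 0.0102, adjusted p = 0.0306, n = 34), but r = 0.266 (permutation p = 0.165) without 100 µg/L. The pooled relation therefore did not pass without the highest concentration. By community, r was smaller without 0 and 100 µg/L in the non-stressed libraries only. The slopes of the 2 communities differed by −0.00822 percentage points per rank, which was not beyond chance (permutation p = 0.988).

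**Figure D5:**
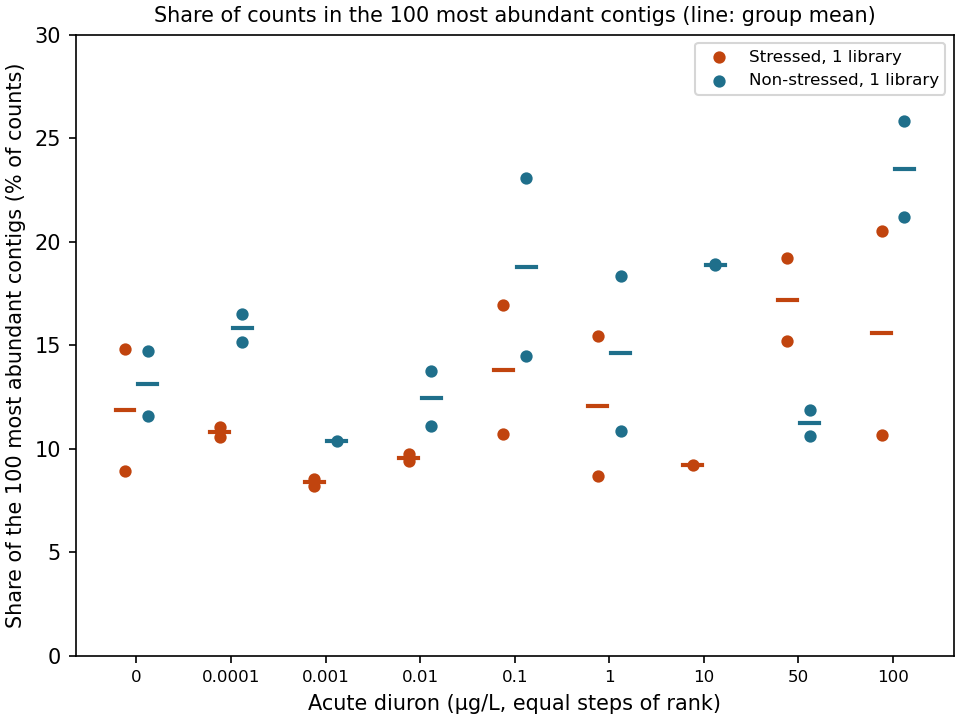
Share of counts in the 100 most abundant contigs of each library (vertical axis, %) against acute diuron in µg/L in equal steps of rank (horizontal axis); points are libraries after thinning to equal totals, lines are group means and colours the communities. The mean share was 13.2% at 0 and 23.5% at 100 µg/L in the non-stressed, and 11.9% and 15.6% in the stressed community.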

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

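The bias-adjusted test, cluster sums for comparisons other than the difference between communities and the trends, cluster sums with the replicate block, every setting of the mean trend, the sets without 2 stressed libraries, the relation pooled within communities, and single libraries left out of the distances and of the diversity measures were chosen after the data were seen. The difference between communities kept within 1.5 times its count of 78,262 under 10 of 12 alternatives, and the 4 contigs named for it kept their direction and their call under each of the 9 alternatives that gave them a value and without each single library. At the depth, spread and number of these libraries, simulated trends of up to 64-fold were not recovered when few contigs carried one; depth alone was not varied. Pseudocounts for normalized values were not varied because the table holds counts, and the gene lists could not be tested under any setting. Where a count moved and no reason is given, the cause was not tested.

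Replicate numbers were not treated as pairs, in the tests of contigs or of the diversity measures. Deviations of same-numbered libraries from their group means correlated between −0.184 and 0.317 over 120 pairs of groups (mean 0.0433), with 75 above 0 and 33 above 0.1. The share of the 100 most abundant contigs was higher in the first library of every group of 2 but the non-stressed at 100 µg/L. A difference tied to the replicate number is therefore not excluded for that share. In the block the 2 lone libraries were taken as replicate 1, as their titles say. With the replicate number as a block, 79,276 contigs differed between the communities, 1 at 0 µg/L, 0 along either trend, 0 in the difference of the trends, 37 and 34 among the concentrations (non-stressed and stressed), 129 along the mean trend and 2 over the 16 contrasts, so the block changed no count of contigs by over 1.5 times. It did so for clusters. Sums over clusters with the block gave 0 at 0 µg/L, 328 clusters among the concentrations in the stressed community, 360 along the mean trend and 48 over the contrasts. Sums over clusters without it gave 0, 430, 145 and 5 in the same order.

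DESeq2's size factors, whose mean over groups differed from the TMM scaling by 0.09 on the log2 scale between the communities, called 55 contigs among the stressed concentrations and 5 over the contrasts, and library totals alone 4 over the contrasts. A minimum count of 50, which left 63,679 contigs to test, called 20,603 contigs between the communities, 59 at 0 µg/L, 5 along the stressed trend, 112 among the stressed concentrations, 327 along the mean trend and 124 over the contrasts. Without a filter 3,482,727 contigs were tested and 210,444 differed between the communities, 1,543 at 0 µg/L, 1,091 along the non-stressed trend, 1,345 along the stressed trend, 720 in the difference of the trends, 37,830 and 51,272 among the concentrations, 3,045 along the mean trend and 3,822 over the contrasts. The bias-adjusted test called 10 contigs at 0 µg/L, 62 and 719 among the concentrations, 530 along the mean trend and 16 over the contrasts. Limma-voom called 19 at 0 µg/L, 70 among the stressed concentrations and 207 over the contrasts. DESeq2 called 9,113 at 0 µg/L, 5,509, 4,891 and 2,248 for the trends and their difference, 5,633 and 12,102 among the concentrations, 12,858 along the mean trend and 25,014 over the contrasts.

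The straight-line model, which pools the spread around the line with that between replicates, called 55, 219 and 67 contigs for the trends and their difference and 9 for the mean trend, and the logarithm of the concentration 52 for the mean trend. Left out of the contrast one at a time, the concentrations 0, 0.0001, 0.001, 1, 10, 50 and 100 µg/L gave mean trends of 41, 352, 39, 190, 145, 0 and 0 contigs. Without the first stressed libraries at 50 and 100 µg/L the counts were 0 at 0 µg/L, 17 and 7 among the concentrations, 5 along the mean trend and 1 over the contrasts, and the rank of the concentration took 4.05% of the distances (permutation p = 0.0634, adjusted p = 0.127). The relation of the share of the 100 most abundant contigs with rank, pooled within communities, had r = 0.332 without these 2 libraries, 0.266 without 100 µg/L and 0.279 without 0 and 100 µg/L.

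Leaving out each library in turn, with a lone library taken to vary like the other groups, gave 69,411 to 82,489 contigs between the communities, 0 to 1 at 0 µg/L, 0 to 1 along the non-stressed trend, 0 to 7 along the stressed trend and 0 in the difference of the trends. It gave 11 to 41 and 6 to 129 among the concentrations, 2 to 269 along the mean trend and 0 to 7 over the contrasts. The rank of the concentration took 4.30% to 5.79% of the distances, 7.80% to 10.9% within the non-stressed and 7.28% to 12.6% within the stressed libraries, where it passed the threshold without the first library at 0 µg/L (permutation test, adjusted p = 0.0373) or the second at 50 µg/L (0.0240). The difference in the share of the 100 most abundant contigs ran from −4.01 to −2.86 percentage points. The difference in contigs with a count ran from −5,575 to 47,570, and was −3,893 without the first non-stressed library at 0.1 µg/L and −4,769 and −5,575 without the first and second non-stressed libraries at 100 µg/L.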

Other observations

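Contigs of 1 assembler cluster mostly moved together between the communities. Of the 8,754 clusters with at least 2 contigs called in the comparison of the stressed with the non-stressed community, 965 (11%) held contigs called in both directions, where shuffling the directions over the same contigs gave 5,091 to 5,262 clusters in 100 shuffles. The contigs that fell along the mean trend were of low abundance, with a median of 0.41 on the log2 CPM scale, against 4.14 for those that rose. Among the 69 falling contigs, 9 were also called higher and 9 called lower in the stressed community, and among the 27 rising contigs 3 and 3. The contig with the largest mean share of counts, TRINITY_DN100304_c4_g1_i1 at 0.583%, did not differ between the communities past the threshold (log2 fold change −0.70, SE 0.37, adjusted p = 0.162), while the next, TRINITY_DN81940_c0_g1_i6 at 0.493%, was lower in the stressed community (log2 fold change −1.83, SE 0.45, adjusted p = 0.00461); these 2 were picked by share after their values were seen.

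In the paragraphs that follow, the tests of acute concentration for the 2 stressed libraries, of opposite directions within clusters, of the shared profile other than its relation to depth, and of shuffled groups for DESeq2, for the difference between communities, for each community's trend and for the adjusted calls of the mean trend were chosen after the result was seen.

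The first stressed libraries at 50 and 100 µg/L resembled the non-stressed community more than the other stressed libraries did. When contigs were called from libraries of other concentrations, with these 2 left out of every fit, their log2 ratios of stressed to non-stressed shares were −0.960 and −0.475, against 0.440 to 2.39 in the other 15 stressed and −3.62 to −1.11 in the 17 non-stressed libraries. A swap between communities would need partners, but 0 non-stressed libraries had a ratio above 0. A wrong label or an admixture would bring the transcripts that are at least 16-fold higher in the non-stressed community. Their level was read as a percentage of the way from the mean stressed to the mean non-stressed level of the fit. Its median was 5.05% and −0.847% in the 2 libraries, against −4.685% to 2.206% in the other 15 stressed libraries. Non-stressed libraries gave at least 31.7%, and the admixture that the shares call for would give at least 22.5% and 15.7%. A wrong label, or an admixture of that size, is therefore argued against. The value at 50 µg/L lay above all other stressed libraries, so a smaller admixture there is not. The acute concentration was argued against by the second libraries at 50 and 100 µg/L, with ratios of 1.45 and 2.31. A difference between the biofilms themselves, or in their handling, may remain as the explanation and was not tested; without these 2 libraries 82,180 contigs differed between the communities.

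The 26 contigs with the same profile over the concentrations in both communities were high at 0.0001 and 0.1 µg/L and low between. This bears only on a response that rises steadily with the concentration, and not on one of another shape. A steady rise forbids it. Their mean level at 1 and 10 µg/L was below that at 0.0001 µg/L by 4.65 and 4.68 on the log2 scale. The changes were −4.65 in the non-stressed and −4.68 in the stressed community, with 0.59 as the SD within groups. Library depth was argued against as well, as the correlation of their mean level with the library total was −0.0703 in the non-stressed (permutation p = 0.787, rho = −0.0441, p = 0.868) and −0.109 in the stressed libraries (p = 0.679, rho = −0.154, p = 0.555), and −0.230 and −0.205 without the 2 libraries farthest from the median total. Their differences between replicates, whose correlation between contigs was not used to choose them, correlated between contigs of different clusters with a median of 0.756, against a 95% point of 0.0910 in 1000 random sets of like abundance. These contigs therefore varied together between replicates as well. The transcripts may come from 1 organism or 1 source of material. Other causes of varying together were not tested, and the random sets were matched for abundance only. A handling batch common to a concentration and acting on most contigs cannot be told apart from chance, because over all tested contigs the 2 communities correlated at the same concentration by 0.0445 on average (one-sided exact permutation p = 0.226), and handling that is shared by all libraries of a concentration is confounded with the concentration itself. Whether such a source is biological, such as an organism living in some of the biofilms, was not tested, since the contigs carry no names.

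Where a cluster held contigs called in opposite directions between the communities, a division of the same reads among similar contigs is a candidate explanation. It would make such contigs vary against each other among replicates, but the median correlation of their residuals was 0.109 (quartiles −0.126 and 0.332), against 0.488 for contigs of a cluster called in 1 direction and 0.0210 for random pairs of called contigs. This lies on neither side of the bounds set for it, so shared reads cannot be told apart from transcripts of different organisms joined in 1 cluster. As sums, 33.1% of these 965 clusters differed between the communities, against 37.9% of all 239,028 clusters tested.

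Regrouping the libraries 100 times, the real groups included, on 5000 random tested contigs gave the following. For the difference between communities, 1 of 100 splits, the real one, gave as many calls (1,314, highest other 2). Shuffling the names over single libraries therefore did not give this count. The splits treat libraries as independent, so a chance difference between tanks is not excluded. For the unadjusted p under 0.05, the mean of the 2 trends gave more contigs than any other split (1 of 100; 724, highest other 639), but that comparison was added after the data were seen. For the non-stressed trend 1 other split gave more contigs than the real one (2 of 100; 532, highest other 685), and neither share is adjusted over the trends tested. Chance is not excluded for the stressed trend (24 of 100; 429, highest other 864) or the difference of the trends (39 of 100; 355, highest other 739). The adjusted calls of the mean trend within these contigs were too few for a count to exclude chance (1, highest other 6; 6 of 100 splits gave as many). DESeq2's calls were passed by another split for the mean trend (229, highest other 241; 2 of 100), and were matched or passed for the non-stressed trend (127, highest other 339; 4 of 100, not adjusted over the trends tested) and more often for the stressed trend (100, highest other 424; 13 of 100). For the last 2 the median split called 30 and 37 contigs with the concentrations shuffled, so DESeq2's counts for the acute trends are not all trends. Single splits that call several times the real count may come from a structure among the libraries other than the concentration, which was not tested.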
